A study of Homo sapiens with 2 samples.

How the data were processed

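Small RNA libraries from 2 samples of SWAN-71 cells were analysed, 1 untreated and 1 treated with IFN-γ for 24 h. Per the labels' protocols, total RNA was isolated with Trizol and libraries were made from 1 µg with the TruSeq Small RNA kit. The labels give 4 h of starvation for the treated cells and a time in plain medium for the control, and do not say whether the control was starved first. Nothing in the labels says how many cultures each library represents.

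According to the series' design text, the authors trimmed adapters and low-quality bases in CLC Genomics Workbench 6.5.1 and mapped the reads to miRBase release 21. The number of mismatches allowed, the use of strand and the treatment of reads that match several miRNAs are not given in the sources used here. The deposited table of all miRNAs gives read counts per mature miRNA for each library, per the file headers. The authors also deposited normalized values for each library as RPM, reads scaled to a common total. These values equalled the counts divided by totals of 2615172 and 1295694 reads within 0.01%, so 577 and 105 reads of those totals are not listed. The authors' signed fold, a score deposited with each miRNA, was the ratio of the RPM values of the IFN-γ over the untreated library, with ratios below 1 written as minus the inverse. The authors' deposited p-values come from a test that is not given in the sources used here. Commas inside larger numbers were removed. Columns are headed by library codes that no label explains, and only the names of the deposited tables pair these codes with the conditions. Although its header describes miRNAs detected in both libraries, 16 rows are listed at 0 in both. No row was at 0 in only 1 library.

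Counts were used as deposited. Scaling factors were computed by the TMM method of edgeR 4.0.16 in R 4.3.3 and were 1.04 for the untreated and 0.966 for the IFN-γ library. The log2 ratio of each miRNA is that of the count plus 0.5 over the effective library size. A miRNA counted as higher or lower when this ratio was at least 2 in either direction and the mean count of the libraries was at least 20. Ratios without the pseudocount carry an exact conditional binomial 95% interval (SciPy 1.17.1), and shares of reads a Wilson 95% interval. Reads carry no molecular identifiers, so intervals cover counting error only. With 1 library per group there is no estimate of the spread between replicates, and no test of the conditions was made. At these depths 1 read is worth 0.382 RPM in the untreated and 0.772 in the IFN-γ library, so the shallower IFN-γ library is the coarser of the pair.

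The miRNAs to be named were set by rule before the data were examined. They are the 10 highest and 10 lowest past 2-fold whose interval excludes 1, the 5 most abundant, and up to 4 per list by abundance. Others are said in the text to have been chosen after their values were seen. The 20 lists cover placental clusters, miRNA families, interferon, inflammation, p53, HLA-G and hypoxia, and markers of blood, stromal, muscle, liver and neuronal cells. Both arms count as members. A list's median was ranked among 10000 random lists matched on 10 bins of abundance.

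Hairpins were matched by name to GENCODE release 29 (GRCh38) for 434 of the 435 tested miRNAs, which gave coordinates, host genes and GC content. The trend on GC content is a local linear fit with tricube weights over the nearest 30% of these miRNAs. Earlier forms of that test took the miRNAs with at least the lowest GC content of the 14 miRNAs past 8-fold, without these 14 (32 miRNAs, median log2 ratio 0.017) and then with them, and were not used to decide because the 14 set the cut. Hairpins sharing at least 16 nt with an annotated small noncoding RNA were recorded. The classes compared had none for nuclear transfer RNAs. Mature sequences were not used here, and no sequence of 28S or 45S ribosomal RNA was used here.

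The procedure was tested on simulated counts with the abundances and depths of these libraries, 435 miRNAs and 200 of them changed. The TMM scale was off by -0.0017 on the log2 scale. The simulated changes were balanced between higher and lower, so this does not measure the error under a one-sided change. Of 50 miRNAs changed 3-fold, 98.0% passed 2-fold in the right direction, as did all 50 changed 4-fold and all 50 changed 8-fold. Of 50 changed 1.5-fold, 1 passed, and of 235 unchanged ones 0 passed. Intervals of the unchanged miRNAs covered the true ratio in 96.2%. The ranking of lists was tried on random normal values instead of the simulated counts. Of 200 random lists with no difference, 5% fell outside the central 95%. Random lists ranked among random lists give about that share by construction, and the spread of the real ratios was not used. The members of these lists were unrelated, so this does not show how lists of related miRNAs behave.

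Alternatives covered median-of-ratios and total-count scaling, totals without the most abundant miRNA, the minimum count, the interval as the criterion, the authors' folds, summed arms and a pseudocount of 2. Leaving out a replicate does not apply with 1 library per group. Python 3.11.15, NumPy 2.4.6 and matplotlib 3.10.9 were used.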

Results

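Mature microRNAs (miRNAs) were counted by small RNA sequencing in SWAN-71, a trophoblast line from early human placenta that was immortalized with telomerase. The design has 2 libraries with 1 per group. The untreated library came from cells held in plain medium for 24 h. The IFN-γ library came from cells given interferon-γ (IFN-γ), a cytokine of activated lymphocytes, at 10 ng per ml for 24 h. Starvation for 4 h preceded the IFN-γ. The labels give 10% fetal bovine serum for both groups. The untreated library held 2614595 reads over the listed miRNAs and the IFN-γ library 1295589. Reads in both libraries were listed for 899 miRNAs, and 435 of them reached a mean of at least 20 reads, the minimum for the comparison. No replicate check of any difference between the libraries was possible, so no p-value was computed, and the intervals given with ratios cover counting error only.

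The comparison asks which miRNAs differed in level between trophoblast cells with and without IFN-γ. At least 2-fold higher in the IFN-γ library were 41 miRNAs, and 14 were at least 2-fold lower. The most abundant of the strongly higher miRNAs was miR-4792, with 244 reads in the untreated and 9401 in the IFN-γ library, a ratio of 83.4 after TMM scaling (log2 6.38, 95% counting interval 6.20 to 6.57). With it stood 13 other miRNAs that were at least 8-fold higher, whereas none was 8-fold lower. The tumour suppressor miRNA miR-34a-5p, a transcriptional target of p53, had 193 and 388 reads, a ratio of 4.35 (3.65 to 5.20). Of the 435 tested miRNAs 302 (69.4%) lay within 1.5-fold, the 5 most abundant among them.

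Of the 10 highest miRNAs, miR-4508 and miR-4488 had 1 read each in the untreated library. They had 78 and 51 reads in the IFN-γ library, and their ratios of 169 (29.4 to 6750) and 110 (18.9 to 4442) are correspondingly uncertain. miR-4634 had 21 and 447 reads, a log2 ratio of 5.49. miR-7704 and miR-6087 were better covered, with 92 and 1415 reads and 121 and 1572 reads, and their log2 ratios were 5.05 and 4.81. miR-5787, miR-4516, miR-4492 and miR-3960 had log2 ratios of 5.09, 4.79, 4.68 and 4.67. The other 4 past 8-fold, named after their values were seen, were miR-3195 (4.31), miR-3656 (4.01), miR-4532 (3.96) and miR-663a (3.85). All 14 together took 0.0225% of the listed reads in the untreated library (Wilson 95% interval 0.0208% to 0.0244%) and 1.10% in the IFN-γ library (1.08% to 1.12%).

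No pair of these 14 hairpins lies within 10 kb on 1 chromosome. In GRCh38 with GENCODE release 29, the hairpin of miR-4792 lies on chromosome 3 at 24521362 to 24521435, in an intron of THRB-AS1 on the opposite strand. The hairpin of miR-7704 lies on chromosome 2 at 176188843 to 176188901, in an exon of HOXD1, and that of miR-3960 on chromosome 9 at 127785833 to 127785923, in an exon of CDK9. miR-5787 maps to an intron of GNAI2 on chromosome 3, at 50227436 to 50227490. miR-6087, on chromosome X at 109054542 to 109054590, overlaps no annotated host gene. The 14 hairpins had a median GC content of 76.6%, against 50.8% for the other tested miRNAs. Each of the 14 is named without an arm, and 4 of them (miR-4792, miR-6087, miR-3656 and miR-4532) have no miRNA gene in the RefSeq table used here.

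**Figure D1:**
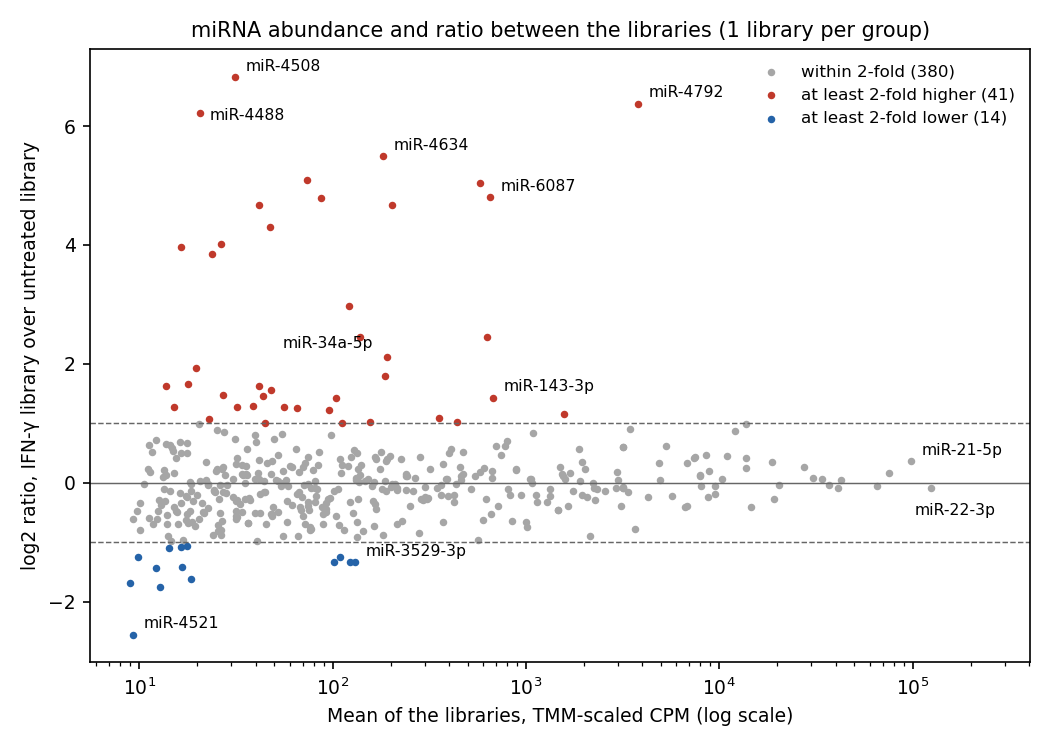
Each point is 1 of the 435 tested miRNAs, placed by its mean TMM-scaled CPM over both libraries (log axis) and its log2 ratio of the IFN-γ over the untreated library; dashed lines mark 2-fold. The 41 higher miRNAs (red) include 14 beyond 8-fold, and the 14 lower ones (blue) reach a log2 ratio of -2.56.

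Among the lower miRNAs, miR-4521 had 44 reads in the untreated and 3 in the IFN-γ library, a ratio of 0.148 (0.0293 to 0.460). The best covered of the 10 lowest were miR-3529-3p with 510 and 93 reads, miR-589-3p with 475 and 87, miR-222-5p with 419 and 81, and miR-4455 with 394 and 72. Their log2 ratios were -1.34, -1.33, -1.25 and -1.33. The hairpin of miR-3529 lies on the strand opposite to a miR-7 hairpin on chromosome 15, and whether the authors' counting used the strand is not given in the sources used here. miR-548t-3p, miR-449c-5p, miR-1276, miR-4448 and miR-3135b had 38 to 76 reads in the untreated library and 5 to 11 in the IFN-γ library. Their log2 ratios ran from -1.75 for miR-548t-3p to -1.42 for miR-3135b. The hairpins of miR-548t and miR-3135b each share at least 16 nt with an annotated small noncoding RNA.

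**Figure D2:**
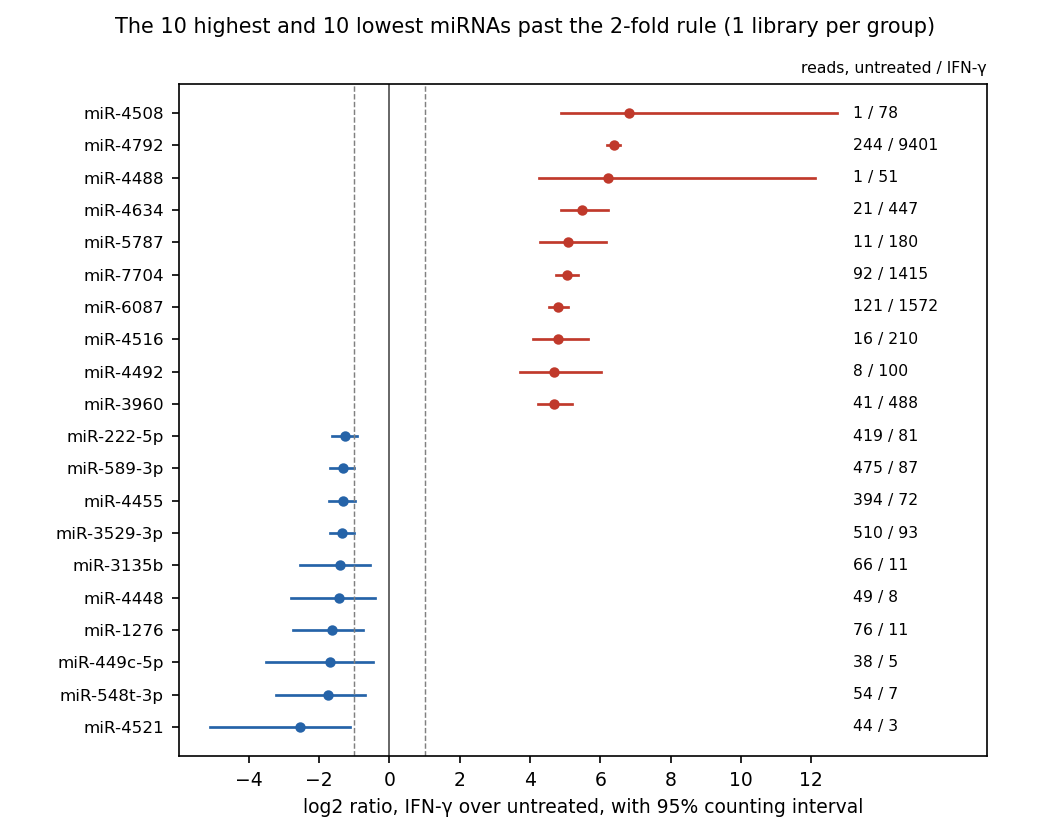
The log2 ratio of the IFN-γ over the untreated library for the 10 highest and 10 lowest miRNAs past 2-fold, with bars for the 95% counting interval and the reads in each library at the right; dashed lines mark 2-fold. Intervals are wide where a library held few reads, as for miR-4508 (1 and 78 reads) and miR-4521 (44 and 3 reads).

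Counting error alone does not give such numbers. In 200 simulations of libraries of these depths with no difference, 0.47 miRNAs on average were 2-fold higher and 1.08 were 2-fold lower, with maxima of 3 and 5. The 95% counting intervals of all 55 miRNAs past 2-fold excluded a ratio of 1. That adds little, since the 2-fold rule and the minimum count on the same reads favour it. The split into higher and lower depends on the scaling. Scaling to total counts lowered each log2 ratio by 0.10 and gave 35 higher and 21 lower, and total counts without the most abundant miRNA gave 35 and 26.

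Both libraries were dominated by the same few miRNAs. miR-22-3p took 13.4% of the reads (Wilson 95% interval 13.35% to 13.43%) in the untreated library and 11.7% (11.7% to 11.8%) in the IFN-γ library. miR-21-5p, which is widely raised in tumours, took 8.86% (8.82% to 8.89%) and 10.7% (10.6% to 10.7%), and its log2 ratio was 0.37. let-7a-5p, a member of a family that restrains growth, took 7.39% (7.36% to 7.42%) and 7.74% (7.70% to 7.79%). By the mean over both libraries, the HOX cluster miRNAs miR-10b-5p and miR-10a-5p followed, with log2 ratios of -0.06 and 0.04, the latter -0.06 under total scaling. These 5 together made up 40.9% (40.9% to 41.0%) of the untreated and 40.5% (40.4% to 40.6%) of the IFN-γ library.

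Of 20 lists of miRNAs fixed before the data were examined, 15 had at least 3 tested members. Both arms of a hairpin count as members, although opposite arms differ in sequence and targets. The lists' median log2 ratio was placed among 10000 random lists of the same size and abundance, as a description of these libraries. For lists of unrelated miRNAs, 0.75 would fall outside the central 95% by chance. Members of 1 family, cluster or hairpin can vary together, so more could fall outside, and the excess cannot be judged. In these data 4 lists were outside. The lowest was miR-17-92 and its paralogues, polycistronic miRNAs that promote the cell cycle, with a median of -0.44 over 15 tested members (percentile 0.16). None of the 15 was past 2-fold, 9 had a counting interval wholly below a ratio of 1, and 4 had one wholly above. miR-20a-5p (3437 and 951 reads) had a log2 ratio of -0.74, while the most abundant members, miR-92a-3p and miR-25-3p, had 0.07 and 0.46, the former turning to -0.03 under total scaling. miR-93-5p stood at -0.08.

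The list was also split by location, after the values were seen, with miRNAs that map to 1 hairpin only. Of the 7 such tested miRNAs from the miR-17-92 hairpins on chromosome 13 (91350605 to 91351391), 6 had intervals below 1, and the median was -0.71. The other, miR-92a-1-5p, had a log2 ratio of 0.17. Left out of the 7 were miR-92a-3p (0.07, with an interval above 1) and miR-19b-3p (-0.81, with an interval below 1), which map both to this cluster and to its paralogue on chromosome X. The 6 tested miRNAs of the paralogous miR-106b-25 hairpins on chromosome 7 (100093560 to 100094074) had a median of 0.13, with 3 intervals above and 2 below 1. The difference between these clusters was not tested.

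The miR-30 family had a median of -0.27 over 11 tested members (percentile 1.5), and 6 of them had an interval below 1 and none above. miR-30a-5p (56876 and 21785 reads), miR-30d-5p, miR-30c-5p and miR-30e-5p had log2 ratios of -0.27, -0.41, -0.39 and -0.18.

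The list of p53 and growth arrest miRNAs had a median of 0.47 over 7 tested members (percentile 98.5). Of its members 2 were at least 2-fold higher, 5 had an interval above 1 and none had one below. miR-34a-5p led with a log2 ratio of 2.12, and miR-192-5p (11266 and 8003 reads), miR-107 and miR-194-5p had 0.62, 0.47 and 0.40. Members outside the naming rule, chosen after their values were seen, follow. The other one past 2-fold, miR-215-5p, had 104 and 115 reads and a log2 ratio of 1.26. The clustered relatives miR-34b-5p and miR-34c-5p had -0.01 and 0.09, the latter -0.01 under total scaling. With the minimum lowered to a mean of 5 reads, the percentile of this list was 97.0, inside the central 95%.

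Markers of stromal and smooth-muscle cells stood at a median of 0.62 over 5 tested members (percentile 98.9), each with an interval above 1. miR-143-3p had 990 and 1234 reads and a log2 ratio of 1.43, and miR-214-3p, the other member past 2-fold and named after its values were seen, had 1.27 from 51 and 57 reads. miR-199a-5p had 0.62. The rows of miR-199a-3p (6809 and 4781 reads) and miR-199b-3p (6814 and 4775 reads) are near-identical copies whose counts differ by less than 1%, and both had 0.60. With 1 row of this pair left out, an alternative chosen after the data were seen, the median was 0.95 over 4 members (percentile 98.6), and with the minimum lowered to a mean of 5 reads it was 1.27 over 7 (percentile 99.96). With the minimum raised to a mean of 100 reads, 4 members were left and the percentile was 94.6, inside the central 95%.

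**Figure D3:**
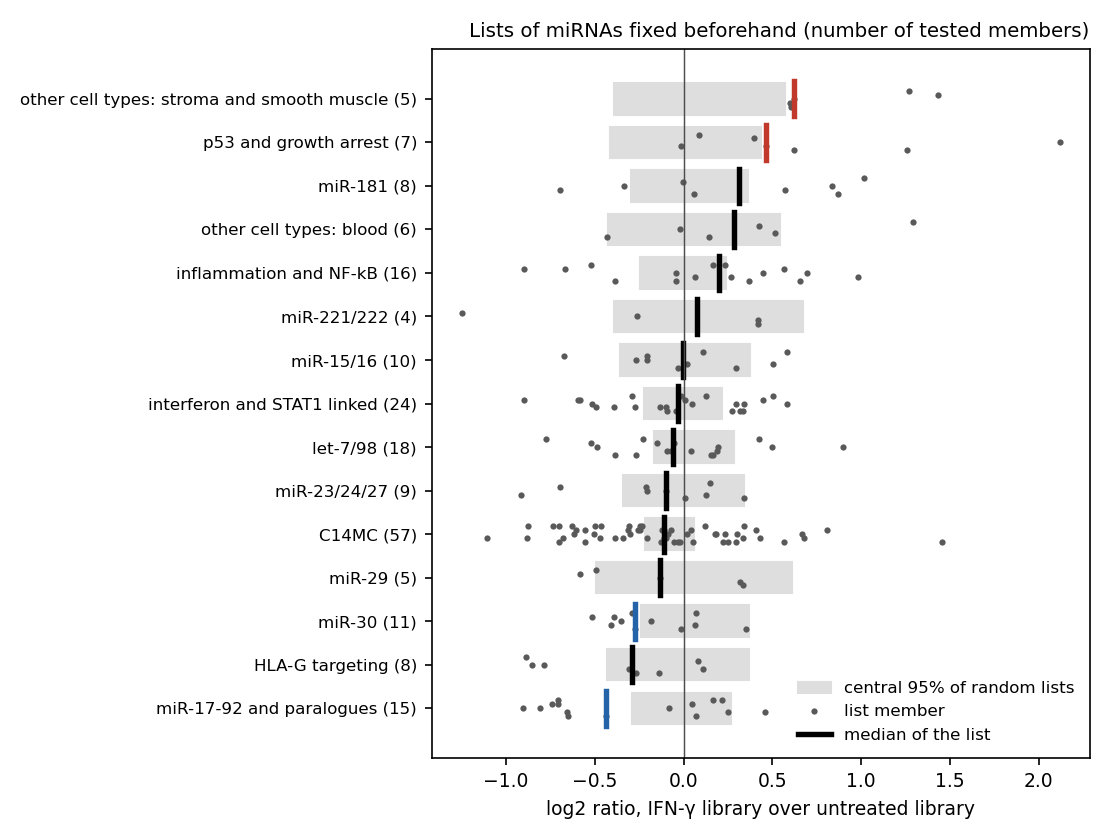
Each grey point is the log2 ratio of 1 tested member of a list fixed beforehand (number of tested members after each name), the thick line is the list's median, and the grey box is the central 95% of 10000 abundance-matched random lists. Medians above the box are red (stroma and smooth muscle 0.62, p53 and growth arrest 0.47) and those below it blue (miR-17-92 and paralogues -0.44, miR-30 -0.27).

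miRNAs linked to interferon signalling and STAT1 stayed near the middle of the random lists. Their median was -0.03 over 24 tested members (percentile 38.4), with 7 intervals above 1, 6 below and 11 spanning it, and at a minimum mean of 100 reads it turned to 0.05. miR-146a-5p (25237 and 15894 reads), a feedback inhibitor of NF-κB signalling, had a log2 ratio of 0.45 and miR-27b-3p 0.34. In contrast, miR-155-5p, an inflammation-linked miRNA, had 7578 and 1878 reads and a log2 ratio of -0.90. The inflammation and NF-κB list, which also holds miR-155 and miR-146a, had a median of 0.20 over 16 tested members (percentile 95.6). At a minimum mean of 5 reads its median was 0.020 (percentile 58.2), and at 100 it was 0.27 (percentile 98.2), outside the central 95%. Within it miR-21-5p had a log2 ratio of 0.37 and miR-21-3p 0.98 (25098 and 22913 reads), neither past 2-fold. The miR-29 family, whose 3p arms target collagen transcripts, had a median of -0.13 over 5 (percentile 26.95), with 0.34 for miR-29a-3p and -0.59 for miR-29a-5p. At a minimum mean of 100 reads only the 3p arms were left, 3 members with a median of 0.32 (percentile 80.8). The list drawn from miRNAs reported to bind the HLA-G 3' UTR, which also holds the opposite arms, had a median of -0.29 over 8 (percentile 10.6), or -0.14 over 5 at a minimum mean of 100 reads. miR-148b-3p, miR-152-3p and miR-148a-3p had -0.14, 0.11 and 0.08, the last -0.02 under total scaling. The opposite arms miR-148b-5p and miR-152-5p, the latter named after its values were seen, had -0.85 and -0.89. Of the 8, these arms and miR-148b-3p had an interval below 1.

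Placental clusters differed in whether they were detected. None of the 37 listed names of C19MC, the primate-specific placental cluster of chromosome 19, was among the 899 miRNAs with reads. The deposited table holds, according to its header, miRNAs detected in both libraries. Its 16 rows at 0 in both libraries were not searched for these names. Reads missing from the table amounted to at most 577 in the untreated and 105 in the IFN-γ library. The cluster of miR-371 to miR-373 had 16 and 6 reads in all. C14MC, the imprinted cluster of chromosome 14, was well represented, with 80938 and 42412 reads and 57 tested members, and its median was -0.11 (percentile 28.7). At a minimum mean of 5 reads the median was -0.24 over 71 members (percentile 2.34), outside the central 95%. Of the 57 members 13 had an interval above 1, 12 below and 32 spanning it, with 0.25 for miR-127-3p and 0.34 for miR-411-5p.

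The other lists were inside the central 95% of random lists or too small to place. The miR-181 family had a median of 0.31 over 8 (percentile 96.0), with 0.87 for miR-181a-5p (23146 and 19541 reads), 0.57 for miR-181b-5p and -0.0047 for miR-181c-5p. At a minimum mean of 5 or of 100 reads its median was 0.57, and its percentiles of 99.2 and 99.9 were outside the central 95%. let-7 and miR-98 had a median of -0.06 over 18 (percentile 19.5), and miR-15/16 had -0.01 over 10 (percentile 48.9), or 0.02 at a minimum mean of 5 or 100 reads. The 9 tested miR-23/24/27 members had a median of -0.10 (percentile 26.1). For miR-221 and miR-222 the median was 0.08 over 4 (percentile 57.6), or -0.02 under total scaling, with miR-221-3p and miR-222-3p both at 0.42 and miR-222-5p at -1.25. Blood-cell markers had a median of 0.29 over 6 (percentile 89.4), with miR-486-5p at 0.52. The hypoxia-induced miR-210-3p had 1240 and 588 reads and a ratio of 1.03 (0.928 to 1.13). Of the epithelial family of miR-200 and miR-141 only miR-200b-3p was tested, with 26 and 17 reads. Of markers of muscle, liver and neurons only both arms of miR-9 were tested, and miR-9-5p had 0.70 from 1643 and 1231 reads.

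The authors' deposited table of differential miRNAs has 232 rows, and these are exactly the miRNAs given a p-value of at most 0.05 in their table of all miRNAs. Although its header names a fold threshold of 2, 161 of the rows have a fold below 2 in either direction. Of the 71 others, 42 have positive and 29 negative folds in the authors' deposited table. All 41 higher and all 14 lower miRNAs are in that table. Of its 232 rows, 12 were below the minimum count, and the others are among the 435 tested miRNAs. The direction was the same for 228 of the 232 rows and differed for 4, whose log2 ratios after TMM scaling were at most 0.07 in size. Neither result is an independent check, because the authors' folds come from the same counts. Their total scaling lowers each log2 ratio by only about 0.10, so few directions could differ. The table's header words the comparison in the opposite order to its folds, which are those of the IFN-γ over the untreated library. The pairing of the library codes with the conditions rests on the names of the deposited tables alone.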

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

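The counts without the 14 miRNAs at least 8-fold higher, those without rows of near-identical counts, and those by total counts without a pseudocount were chosen after the data were seen. The number of higher miRNAs was 28 to 41 and that of lower ones 11 to 21 under the alternatives that moved neither by over 1.5 times. This range is narrow by definition, as the alternatives were grouped by that outcome. Over all alternatives the numbers ran from 20 to 184 higher and from 3 to 58 lower. The alternatives in the group were median-of-ratios and total scaling, summed arms, a pseudocount of 2 and the leaving out of either set of miRNAs. Under total scaling 35 of the 41 higher and all 14 lower miRNAs were kept, the latter because that scaling lowers every log2 ratio. With no minimum count there were 184 higher and 58 lower (242 in all), and with a minimum mean of 100 there were 20 and 4 (24 in all), which follows from the number of miRNAs admitted. Requiring the whole counting interval beyond 2-fold left 25 and 3 (28 in all), a stricter rule by construction. Totals without the most abundant miRNA lowered log2 ratios by 0.13 and gave 26 lower, and the authors' deposited folds gave 25. The latter follows from their construction, since total counts without a pseudocount gave 23 lower, and 25 once ratios were rounded to 2 decimals. Of the 247 miRNAs whose interval excluded 1, 216 were in the authors' deposited table, and without a minimum count 67 of 242. The number of lists outside the central 95% stayed at 4 to 5. Another scaling shifts all log2 ratios by the same amount, so percentiles could hardly move, and they moved by at most 0.44. The scalings are therefore no check on the lists. At a minimum mean of 5 or 100 reads, 3 of the 4 lists stayed outside. At 5 the C14MC list was added at percentile 2.34, and the inflammation and NF-κB list, at 95.6 with the minimum of 20, was at 58.2. At 100 the latter was at 98.2. At both, the miR-181 list was added, as it also was without the 14 miRNAs at least 8-fold higher (percentile 97.53). Of 256 values of list medians and named miRNAs under the alternatives, 161 stayed within the counting interval and 95 moved beyond it. Part of the 161 could not move, since no list holds any of the 14 miRNAs at least 8-fold higher. Leaving out rows of near-identical counts could likewise change only the stromal list. Whether a named miRNA moved under another scaling follows from the width of its counting interval. Sign changed for 5 of 83 named miRNAs, whose log2 ratios were at most 0.08 in size, and for the medians of 4 of 15 lists, 0 of them outside the central 95%. No named miRNA past 2-fold changed sign, which a shift of at most 0.10 could not bring about. Depth limits both extremes, since 6 of the 10 lowest had at most 11 reads in the IFN-γ library and 4 of the 10 highest in the untreated library.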

Other observations

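The tests of GC content, of counting error and of clusters and families were chosen only after the result was seen, that of GC content as the third form tried, as were the miRNAs of the next paragraphs.

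Of the 27 miRNAs between 2-fold and 8-fold higher in the IFN-γ library, some are given here with their host genes, and no link to host genes was tested. miR-33a-5p, from an intron of the sterol regulator gene SREBF2 on chromosome 22, had 66 and 90 reads and a log2 ratio of 1.56. miR-33b-5p, from an intron of SREBF1 on chromosome 17, had 39 and 50 reads and a log2 ratio of 1.47. miR-1908-5p, which overlaps an exon of the fatty acid desaturase gene FADS1 on chromosome 11, had 89 and 100 reads and a log2 ratio of 1.28. Both arms of miR-582, from an intron of PDE4D on chromosome 5, were higher, with 1.93 for miR-582-5p and 1.63 for miR-582-3p. miR-335-3p, from an intron of the imprinted gene MEST, had 225 and 362 reads and a log2 ratio of 1.80, whereas miR-335-5p from the same hairpin had 0.21 (ratio interval 0.902 to 1.47).

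Some neighbouring or related miRNAs had similar values. On chromosome 21 (16539089 to 16539911) miR-99a-5p had a log2 ratio of 1.00 and let-7c-5p (6557 and 5638 reads) 0.90, above let-7a-5p at 0.17. All 6 tested miRNAs of the miR-424 and miR-503 cluster on chromosome X (134540185 to 134546711) had ratios above 1, with a median of 0.28, and 2 intervals excluded 1. In the miR-378 family, miR-378c, miR-378d and miR-378e had 1.02, 1.22 and 1.67, whereas the far more abundant miR-378a-3p (8009 and 3821 reads) had 0.05, or -0.05 under total scaling. The 6 tested miR-548 members had log2 ratios of -1.75 to -0.64, with a median of -0.84, and 1 of them was past 2-fold. These families hold closely related sequences, so reads assigned to their members are uncertain.

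The first pattern weighed is the set of 14 miRNAs at least 8-fold higher. Counting error is argued against by the 200 simulations with no difference, in which at most 3 miRNAs were even 2-fold higher. The smallest lower 95% bound of the ratio among the 14 was 6.65. That bound adds little, since the 8-fold rule and the minimum count on the same reads favour it. A rise of small noncoding RNA fragments is left undecided, because only annotated RNAs were compared and mature sequences were not used. Of the 14 hairpins, 0 share 16 nt with an annotated one, so no source among the classes compared was found for them. Those classes did not include nuclear transfer RNAs. The 21 other tested miRNAs that do share 16 nt had a median log2 ratio of -0.042 (quartiles -0.45 and 0.39). Of these, miR-1246 (2.45) and miR-1273g-3p (1.08) were past 2-fold higher, and miR-548t-3p and miR-3135b past 2-fold lower. The 21 match RNAs of several kinds, so their median cannot speak for each kind. A GC-dependent recovery stays open, as neither value decides it: subtracting a local trend on hairpin GC content took the median of the 14 from 4.80 to 2.63, but the 14 shaped that trend, and the 32 other tested miRNAs of at least their lowest GC content had a median of 0.017 (quartiles -0.27 and 0.39), but leave out the 14. It remains possible that the reads come from other GC-rich transcripts, such as 28S ribosomal RNA, which was not tested. An effect of IFN-γ may also underlie the set. With 1 library per group it cannot be told apart from a difference between the preparations. Nor can it be told apart from the 4 h of starvation, which the labels give for the treated cells only.

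The second pattern is the similar ratios of miRNAs from 1 genomic cluster. Only pairs of different families were used, told apart by the number in the miRNA name alone. Relatives such as miR-221 and miR-222 were thus compared as different families. Over 22 clusters, in which each hairpin lay within 10 kb of the next, the mean absolute log2 difference was 0.42. Against shuffles over all tested miRNAs it fell at percentile 0. That comparison drew in the 14 extreme miRNAs, which are in no cluster pair, and a shuffle among the participating miRNAs, chosen after the former was seen, put it at percentile 5.77 (median of shuffles 0.50). A shared primary transcript may contribute, but at this value it cannot be told apart from chance, nor from related sequences among the pairs. Same-family miRNAs of different loci were closer than shuffled ones, with a mean difference of 0.46 against 0.63 (percentile 0.34, or 0.09 over all tested miRNAs), which is consistent with reads shared between similar sequences or with common regulation.

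The third pattern concerns hairpin arms, as with miR-222-5p at -1.25 beside miR-222-3p at 0.42. In 95 hairpins with both arms tested, the less abundant arm had the lower ratio in 55 and the higher in 40, with a median difference of -0.10. Random pairs matched on the abundance of both arms gave -0.28 to 0.09, and the observed value was at percentile 46.5 among them. The difference is therefore in the range that pairs of the same abundances give. That range also includes no difference between arms, so the test cannot tell a trend with abundance from no pattern. A change of arm selection was not tested for single hairpins.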
